A study of Mus musculus with 8 samples.

How the data were processed

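Total RNA from 8 mouse stomach samples, 4 gastric adenocarcinomas and 4 samples of normal gastric mucosa, was measured on Affymetrix expression arrays. RNA was isolated with a Qiagen kit and labelled with biotin, per the labels' protocols. The series description states that the tumours arose in transgenic animals and were frozen fresh. The labels name no transgene, sex, age or strain, and do not say whether the 8 samples come from separate animals. The p-values therefore measure only the spread between these samples, which may be partly technical. Groups and replicate numbers were taken from the labels.

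The deposited values are log2 expression values made with RMA (robust multi-array average, which corrects background, normalises the arrays to a common distribution and summarises the probes of each probe set), per the submitters' processing notes. The version, the scanner files and the normalisation settings are not given in the sources used here. The authors rounded the values to 1 decimal: 284448 of 284448 values had at most 1 decimal (tolerance 1e-06). The annotated table and the series' value table held the same 284448 values, with 0 differences, so only the annotated table was used. It held 35556 probe sets. Of these, 28350 were gene probe sets and 7206 were controls or other types and were left out. Of the gene probe sets, 24975 carried 1 symbol, 2 carried several and 3373 carried none, 29 of them with an empty symbol cell. Among those 29, 25 were described as septin or membrane-associated ring finger genes, whose symbols resemble dates. Gene names and positions are those of the deposited table. Of the probe sets, 22243 matched a newer name by accession in a reference table of assembly GRCm38.p6, and for 2241 the newer symbol differed. Only 11.4% of 21439 probe sets overlapped their gene's position in that assembly. The positions printed here are therefore from another build, which is not given in the sources used here. Slide and scan dates were not used here, so no batch could be tested.

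Each of 21626 genes was represented by its probe set with the highest mean over the 8 arrays (1799 genes had over 1 probe set), with no filter on dim genes. Adenocarcinoma was compared with normal mucosa by limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Gene changes are log2 differences, adenocarcinoma minus normal mucosa, with the model's SE. The number of arrays, 4 per group, limits the precision. A total of 37 gene lists (cell types of the stomach and its neighbours, stroma, immune cells, signalling pathways, metabolism and the cell cycle) were tested with camera, which compares the genes of a list with all other genes, at a preset correlation of 0.01 between genes. The test was repeated with an estimated correlation. It was also repeated with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Lists with at least 4 measured genes were tested. Gene ontology terms in the deposited table with 15 to 300 tested genes were tested in the same way. The spread within each group was the median over genes of the SD between its 4 arrays. The ratio of both medians was tested by a two-sided exact permutation of the arrays, each centred on its group mean, over 70 assignments.

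Named genes were the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, 2 called members of largest change per list (the member with the smallest p where none was called), and Trp53, Cdh1 and Smad4. Some genes chosen by this rule are not reported here. Lists, tests, this rule and the first set of alternatives below were chosen before the data were examined. Other list members and gene families are given as examples chosen after their values were seen. The alternatives were median centring of each array, cyclic loess, 32 intensity units added to each value before log2, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, eBayes with trend and robust, array weights (statmod 1.5.0), the replicate number as a block, each array left out in turn, and an adjusted p under 0.01. Added after seeing the data were tests without genes on X and Y, on probe sets marked unique, with seeded noise of plus or minus 0.05 to undo the rounding, and with arrays centred on the olfactory and vomeronasal receptor genes.

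The code was tested on simulated data for 21626 genes, with independent noise at each gene's SD pooled over both groups and 200 changed genes. In the data 41.8% of genes were called and the groups differed in spread, so the rates below need not hold there. It recovered 25.4% of changes of 0.5 on the log2 scale (17 of 67), 74.6% of changes of 1 (50 of 67) and 97% of changes of 2 (64 of 66). Of 136 genes called, 5 were unchanged. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.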

Results

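Gene expression was profiled in 4 primary gastric adenocarcinomas of transgenic mice and in 4 samples of normal gastric mucosa. The medians of their log2 RMA values lay between 7.8 and 8.0. Those of their background control probes were 6.0 to 6.2 in adenocarcinoma and 6.2 to 6.4 in normal mucosa. The median of exon control probes minus that of intron control probes, a measure of array quality, was 3.9 to 4.5 in adenocarcinoma and 3.6 to 4.0 in normal mucosa, so array quality may differ with the groups, which was not tested. Over 21626 genes, Pearson's r lay between 0.961 and 0.976 among adenocarcinomas, between 0.99 and 0.994 among normal samples and between 0.899 and 0.923 across groups. These correlations are across genes, which are not independent replicates.

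The comparison asked which genes differ between gastric adenocarcinoma and normal mucosa. In the adenocarcinomas, genes of acid- and enzyme-secreting stomach cells fell, while genes of fibroblasts, vessels, macrophages and dividing cells rose. With an estimated correlation none of these gene lists passed (smallest adjusted p = 0.11, parietal cells). The antimicrobial lectins Reg3g and Reg3b had the largest measured rises, by 6.05 ± 0.369 and 5.80 ± 0.3 on the log2 scale (66.3-fold and 55.7-fold). The gastric gasdermin Gsdma2 (-6.23 ± 0.493) and the acidic chitinase Chia (-6.03 ± 0.356) had the largest measured falls. Each of these 4 genes parted all 4 adenocarcinomas from all 4 normal samples, with limma adjusted p of 6.23e-06, 2.65e-06, 2.84e-05 and 5.37e-06. In the deposited table Reg3g (probe set 10545569) lies on chromosome 6 from 78416262 to 78418868, near Reg3b (10539179; 78320879 to 78323460), Gsdma2 (10380965) on chromosome 11 from 98508073 to 98519278, and Chia (10495136) on chromosome 3 from 105916300 to 105935038.

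The other leading rises were the acute-phase protease inhibitor Serpina3n (5.18 ± 0.325), the metalloproteinase inhibitor Timp1 (5.10 ± 0.191), the Y-linked Eif2s3y (5.03 ± 0.347), the complement C1 inhibitor Serping1 (4.85 ± 0.244), the matrix proteoglycan Lum (4.85 ± 0.261) and Ly6a, a surface antigen also called Sca-1 (4.80 ± 0.369). The other leading falls were Xist (-5.90 ± 0.221), both subunits of the proton pump of parietal cells, Atp4b (-5.88 ± 0.194) and Atp4a (-5.28 ± 0.204), the protein disulfide isomerase Pdia2 (-5.70 ± 0.220), the acyltransferase Mogat1 (-5.48 ± 0.270) and the potassium channel Kcnj16 (-5.45 ± 0.124). All 12 changes had adjusted p of 2.46e-05 or less in limma, and their groups did not overlap. In normal mucosa, Eif2s3y and Lum lay at or below the median background probe on all 4 arrays, as Gsdma2 did in 3 of 4 adenocarcinomas and Reg3g in 1 of 4 normal samples. Their differences, like those given below for Uty, Il1a, Ddx3y and Cxcr2 (4, 4, 3 and 3 normal arrays) and Fabp1 (2 adenocarcinomas), are therefore limited by background and no exact measure of change.

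In all, 3942 genes rose and 5099 fell, 41.8% of those tested. The rises were larger, with a median of 1.71-fold against 1.34-fold for the falls, and 1434 genes rose and 682 fell at least 2-fold. The groups did not overlap for 7411 genes (34.3%), against 2.86% by chance. The share of calls that were rises was 43.6%. It moved with the scaling of the arrays, to 24.8% after median centring, 54.8% after cyclic loess and 76.6% after centring on receptor genes, which placed the median change of all genes at -0.238, -0.00559 and 0.0771 on the log2 scale instead of -0.1. Among 2-fold calls the share was 67.8%, against 57.8% after median centring, 67.7% after cyclic loess and 80.2% after centring on receptor genes. The number of genes lower fell to 2976, 3004 and 2975 without normal replicates 1, 3 and 4, and to 3384 without adenocarcinoma replicate 2.

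**Figure D1:**
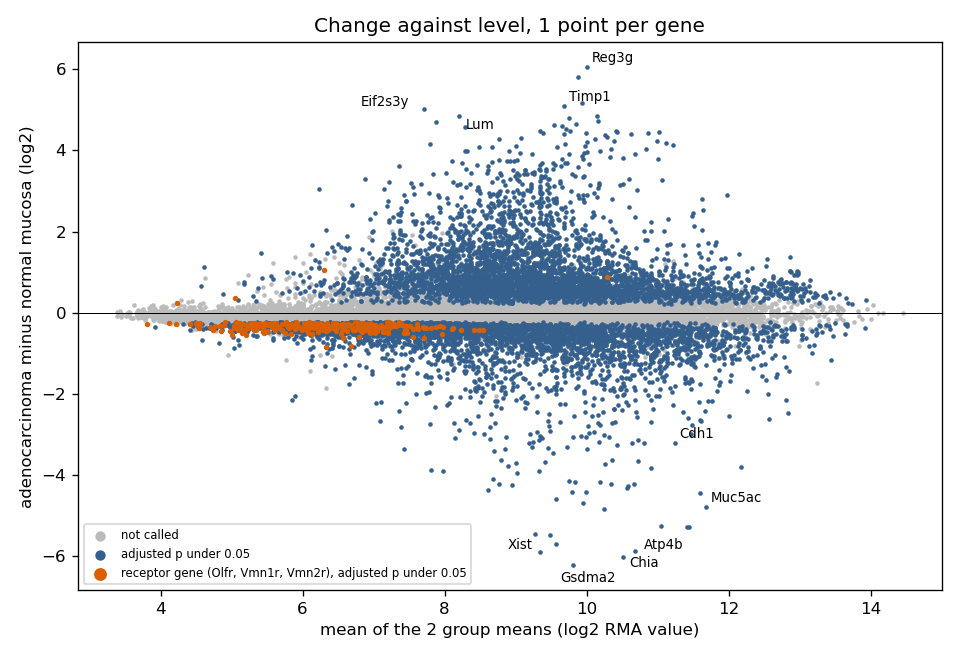
Change of each gene (adenocarcinoma minus normal mucosa, log2) against its level (mean of both group means, log2 RMA value), with called genes in blue and called olfactory and vomeronasal receptor genes in orange. Rises reach 6.05 (Reg3g) and falls -6.23 (Gsdma2), and the orange points lie mostly at small falls of dim genes.

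Sex-linked genes parted the groups. Xist, the RNA that silences one X chromosome in females, was at 6.40 ± 0.183 in adenocarcinoma and 12.3 ± 0.483 in normal mucosa (SD, n = 4 each; limma adjusted p = 3.9e-07). The Y-linked genes Eif2s3y, Uty (4.70 ± 0.320), Ddx3y (3.98 ± 0.283) and Kdm5d (2.33 ± 0.272) were higher in all 4 adenocarcinomas than in any normal sample. The last 3 were chosen after their values were seen. In normal mucosa Eif2s3y and Uty lay at or below the median background probe on all 4 arrays. This is the pattern of male adenocarcinomas and female normal samples, so these differences need not come from the tumours. The labels give no sex, age or transgene and do not say whether the normal samples came from transgenic animals. Sex, and any difference in age or genotype, therefore cannot be told apart from tissue in any change given here. Of the 9041 called genes, 8721 lie on neither X nor Y, about the share among all genes tested (20776 of 21626). This count therefore does not limit the part that sex may play.

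Genes of the specialised cells of the gastric glands fell together. Of 18 parietal cell genes, 17 fell (17 adjusted over the list alone), with a median of -1.61; besides the proton pump and Kcnj16 they included the nuclear receptor Esrrg (-4.60) and the histamine receptor Hrh2 (-1.55), while the potassium channel Kcnq1 was at -0.03 (adjusted p = 0.936). All 7 measured chief cell genes fell (7 adjusted over the list alone; median -3.35), among them Chia, Pdia2, the intrinsic factor gene Gif (-4.28) and the pepsinogen gene Pgc (-2.48). Of 14 pit cell genes, which mark the mucus-secreting surface, 12 fell (13 adjusted over the list alone; median -1.45). The mucin Muc5ac dropped from 14.08 ± 0.05 to 9.28 ± 1.74 (SD, n = 4 each) and Psca fell by 4.45 ± 0.564. Camera gave adjusted p of 1.39e-12, 7.69e-06 and 1.84e-05 for these 3 lists, and adjusted p = 0.11, 0.24 and 0.32 with an estimated correlation.

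Other epithelial lists were mixed. Of 5 mucous neck cell genes, 2 fell, including the glycosyltransferase A4gnt (-1.98 ± 0.422), and Gkn3 rose (1.75 ± 0.360; list camera adjusted p = 0.504; 1 rose and 2 fell adjusted over the list alone). Of 18 endocrine genes, 6 fell, led by ghrelin (Ghrl, -4.33 ± 0.334) and somatostatin (Sst, -3.20 ± 0.293), and 1 rose (6 and 1 adjusted over the list alone). The endocrine list passed after centring on receptor genes (0.0114) by fry (0.0157) and without adenocarcinoma replicate 2 (0.0394) or normal replicate 1 (0.0301), but not in the main camera test (adjusted p = 0.124). Of 12 genes of spasmolytic polypeptide-expressing metaplasia, a mucous lineage that appears when parietal cells are lost, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 1.37, camera adjusted p = 0.000971, adjusted p = 0.20 with an estimated correlation). They included the chloride channel Cftr (4.10 ± 0.581), the hyaluronan receptor Cd44 (3.98 ± 0.296) and Wfdc2 (3.28 ± 0.247), while Tff2, which names the lineage, fell by 0.53 ± 0.155. Intestinal genes went both ways, with 5 up and 2 down of 17 (the same counts adjusted over the list alone; adjusted p = 0.643). The lipid carriers Fabp2 (-3.78 ± 0.275) and Fabp1 (-2.43 ± 0.261) fell, and the antigen Gpa33 rose (1.48 ± 0.228). This list's median was -0.225 and its mean -0.101, while its test pointed up.

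The adhesion molecule E-cadherin, encoded by Cdh1 (probe set 10575052) on chromosome 8 from 109127268 to 109194146 in the deposited table, stood apart from other epithelial genes. Cdh1 was at 9.63 ± 0.954 in adenocarcinoma and 12.85 ± 0.0577 in normal mucosa (SD, n = 4 each), 9.35-fold lower, with a limma adjusted p of 0.000354. Of 23 epithelial junction and keratin genes, 5 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.919). Desmoplakin (Dsp) fell by 1.08 ± 0.123, whereas the tight junction claudins Cldn7 (3.35 ± 0.169) and Cldn4 (3.15 ± 0.229) rose. The keratin Krt8 was at 13.8 ± 0.0816 and 13.88 ± 0.05 (adjusted p = 0.46). The list's median was -0.125, its mean 0.0728 and its test upward, and the test turned downward after cyclic loess (0.581) and after centring on receptor genes (0.914).

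**Figure D2:**
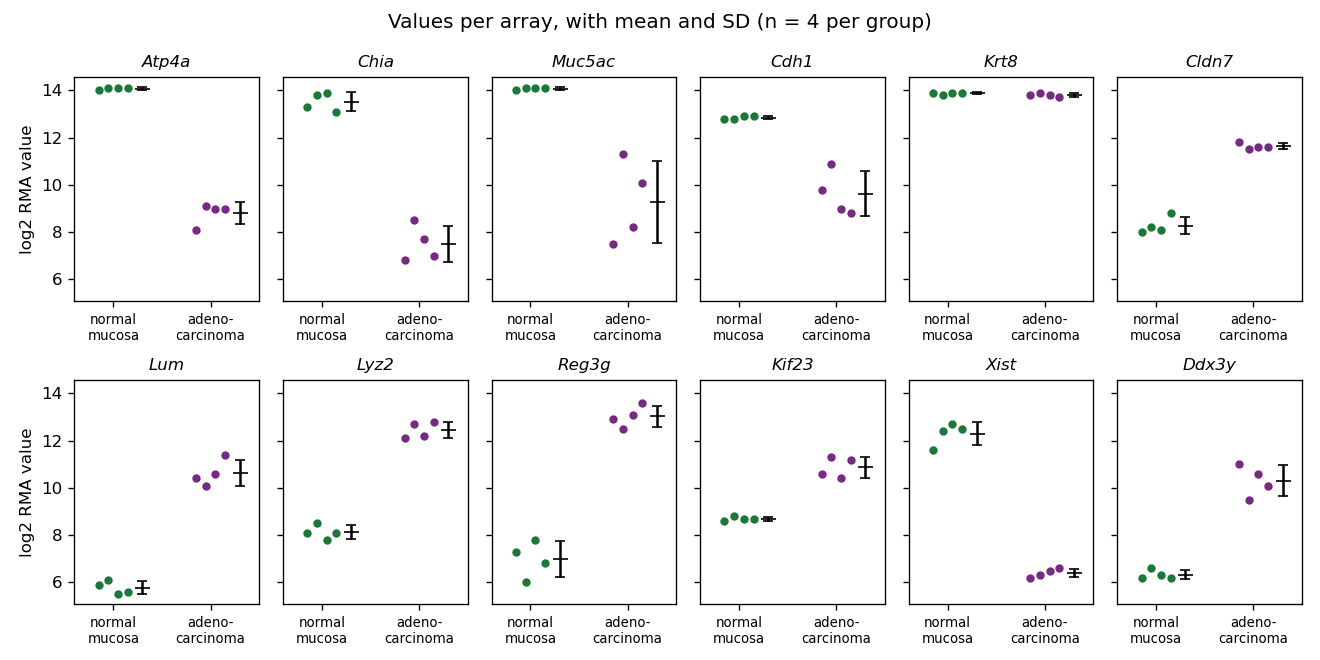
Log2 RMA values of 12 genes in each of the 4 normal (green) and 4 adenocarcinoma (purple) samples, with bars for the mean and SD. Krt8 overlaps between groups, while the other 11 genes do not.

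Many stromal genes rose. The normal samples are labelled mucosa, and whether the tumour samples held more of the deeper stomach wall was not tested. Of 29 genes of fibroblasts and extracellular matrix, 28 rose (28 adjusted over the list alone; median 3.03, camera adjusted p = 1.02e-20, adjusted p = 0.20 with an estimated correlation). They included Lum, the collagen Col12a1 (4.63 ± 0.285) and fibronectin (Fn1, 4.45 ± 0.324). The exception was Fbln1 (-0.60, adjusted p = 0.19). Of 19 matrix proteases and inhibitors, 16 rose (17 adjusted over the list alone; median 2.02, 4.24e-13), among them Timp1 and the matrix metalloproteinase Mmp7 (4.53 ± 0.251), with adjusted p = 0.20 with an estimated correlation. Among 13 mesenchymal transition factors, 8 rose (9 adjusted over the list alone; median 0.70, 2.65e-06, and adjusted p = 0.24 with an estimated correlation). Vimentin (Vim, 3.80 ± 0.221), cadherin-11 (Cdh11, 3.45 ± 0.175) and the E-cadherin repressor Zeb2 (2.45 ± 0.110) rose, while the repressor Snai2 was level (0, adjusted p = 1). Endothelial genes rose in 13 of 14 cases (14 adjusted over the list alone; median 1.75, 1.11e-10, and adjusted p = 0.27 with an estimated correlation), led by Emcn (4.08 ± 0.222) and VE-cadherin (Cdh5, 3.93 ± 0.243). Of 16 smooth muscle genes, 9 rose (9 adjusted over the list alone; median 1.24, 0.000372, and adjusted p = 0.62 with an estimated correlation), among them Acta2 (3.83 ± 0.284) and desmin (Des, 3.43 ± 0.660). Desmin was at 12.0 and 12.2 in adenocarcinoma replicates 2 and 3 but at 8.8 in replicate 1.

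Among leukocyte lists, those of macrophages and monocytes and of neutrophils rose. Of 20 macrophage and monocyte genes, 19 rose (19 adjusted over the list alone; median 2.35, camera adjusted p = 3.1e-15, adjusted p = 0.20 with an estimated correlation), led by lysozyme (Lyz2, 4.33 ± 0.197) and the complement component C1qb (3.80 ± 0.153). Of 13 neutrophil genes, 10 rose, including lactoferrin (Ltf, 2.78 ± 0.450) and the chemokine receptor Cxcr2 (2.75 ± 0.176), and 2 granule genes, Camp and Mpo, fell (11 and 2 adjusted over the list alone; median 1.55, 0.000128, and adjusted p = 0.33 with an estimated correlation). Of 27 cytokine and chemokine genes, 13 rose and Ifng fell by 0.35 (13 and 1 adjusted over the list alone; median 1.12, 2.44e-06, and adjusted p = 0.46 with an estimated correlation). Lipocalin-2 (Lcn2, 4.65 ± 0.269) and interleukin-1 alpha (Il1a, 4.58 ± 0.538) led them, and Il6 ranged from 5.4 in adenocarcinoma replicate 1 to 9.9 in replicate 3.

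The lymphoid and mast cell lists gave few calls. Of 19 T and NK cell genes, none rose and 2 fell, Cd8a (-0.40 ± 0.0888) and Nkg7 (-0.35 ± 0.120), and 1 fell adjusted over the list alone (camera adjusted p = 0.693). Neither fall was called after centring on receptor genes (0.0756 and 0.412), and that of Nkg7 was also lost after cyclic loess (0.456), with array weights (0.0874), with added noise (0.0524) and in 7 of the 8 leave-outs, all but that of adenocarcinoma replicate 4 (0.0535 to 0.0922). Of 10 B and plasma cell genes, 2 rose (1 adjusted over the list alone): the antibody J chain Igj (3.18 ± 0.302) and the B cell receptor component Cd79b (1.20 ± 0.426). The list passed with an adjusted p of 0.0329 (median 0.437; adjusted p = 0.72 with an estimated correlation) but not without adenocarcinoma replicate 2 (0.144), adenocarcinoma replicate 3 (0.0532), normal replicate 2 (0.0633) or the dimmest 30% of genes (0.172), nor after centring on receptor genes (0.106) or by fry (0.141). Cd79b was not called after median centring (0.0516), cyclic loess (0.0581) or 32 units added (0.0614), with trend and robust (0.0621), a replicate block (0.0987) or added noise (0.0537), or in 7 of the 8 leave-outs, all but that of adenocarcinoma replicate 1 (0.0573 to 0.11). Of 13 antigen presentation genes, 5 rose, led by the class II genes Cd74 (2.13 ± 0.460) and H2-Aa (1.83 ± 0.485), and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.147; 0.0322 without adenocarcinoma replicate 1). H2-Aa was not called without normal replicate 1 (0.0514) or 3 (0.0547). Of 21 interferon response genes, 10 fell, led by Oas2 (-1.93 ± 0.201) and Usp18 (-1.25 ± 0.292), and 2 rose (10 and 2 adjusted over the list alone; median -0.475, adjusted p = 0.0776). The interferon list passed after cyclic loess (0.0351), centring on receptor genes (0.00568), by fry (0.025), without the dimmest 30% of genes (0.0235), and without adenocarcinoma replicate 2 (0.0223) or normal replicate 3 (0.0271). Of 10 mast cell genes only Ms4a2 fell, at or below background on all 8 arrays (1 adjusted over the list alone; adjusted p = 0.662).

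Genes of dividing cells rose. All 30 mitosis genes rose (30 adjusted over the list alone; median 1.17, camera adjusted p = 3.1e-15, adjusted p = 0.31 with an estimated correlation), with the largest changes in the spindle motor Kif23 (2.18 ± 0.195) and the checkpoint kinase Bub1 (2.08 ± 0.160). Of 30 DNA replication genes, 19 rose, including the polymerase Pole (1.20 ± 0.276) and the clamp loader Rfc4 (1.13 ± 0.146), and Ccne2 fell by 0.40 (23 and 1 adjusted over the list alone; median 0.625, 2.58e-07, and adjusted p = 0.46 with an estimated correlation). Genes of oxidative phosphorylation and the citric acid cycle moved the other way. Of 33, 28 fell (30 adjusted over the list alone; median -0.55, 1.18e-07, and adjusted p = 0.36 with an estimated correlation), led by Ndufs1 of complex I (-1.15 ± 0.207) and Ogdh (-1.05 ± 0.133). Of 22 hypoxia and glycolysis genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.267). The lactate exporter Slc16a3 rose by 1.60 ± 0.293 and Car9, a carbonic anhydrase also made by normal gastric epithelium, fell by 3.15 ± 0.552.

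**Figure D3:**
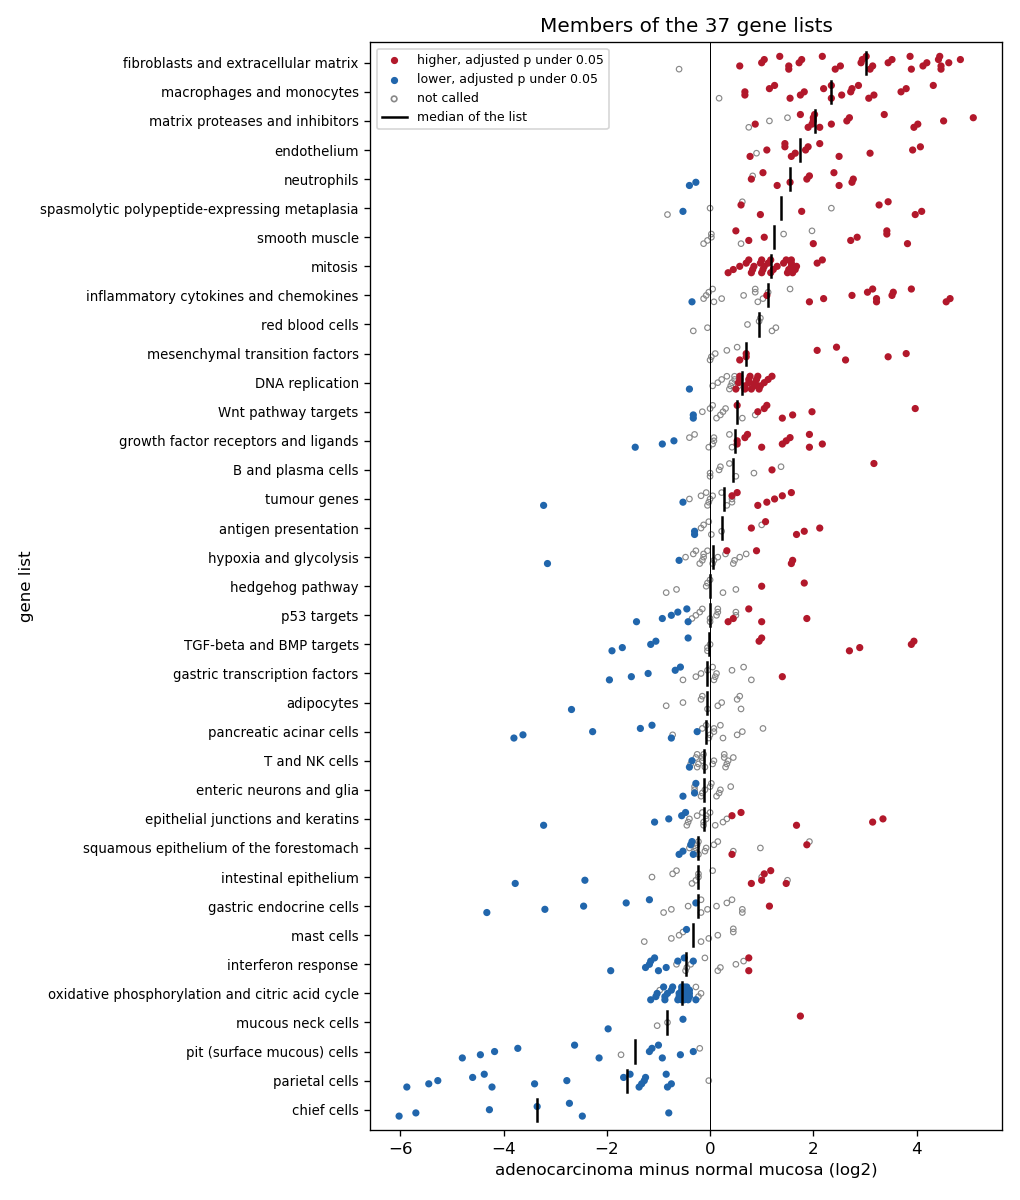
Change of each measured member (adenocarcinoma minus normal mucosa, log2) of the 37 gene lists, ordered by median (black bar), with called rises in red, called falls in blue and genes not called as open circles. Medians run from -3.35 (chief cells) to 3.03 (fibroblasts and extracellular matrix).

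Among signalling lists, 8 of 19 Wnt pathway targets rose and 2 fell (8 and 2 adjusted over the list alone; median 0.525, camera adjusted p = 0.00125, adjusted p = 0.31 with an estimated correlation). Cd44, Ephb2 (1.98 ± 0.175) and the stem cell receptor Lgr5 (1.60) rose, and of the Wnt inhibitors Notum and Dkk1 fell by 0.325 each while the related Dkk2 rose (1.40). Of 22 growth factor receptors and ligands, 11 rose, led by epiregulin (Ereg, 2.18 ± 0.321) and hepatocyte growth factor (Hgf, 1.93 ± 0.202), and 3 fell. The falls were in other ligands of the EGF family, Egf (-1.45), Areg (-0.925) and Tgfa (-0.70), while Hbegf of that family rose (0.725). The list (11 and 4 adjusted over the list alone; median 0.475) had an adjusted p of 0.0271, adjusted p = 0.31 with an estimated correlation, and was not called after cyclic loess (0.153), centring on receptor genes (0.0972) or without the dimmest 30% of genes (0.172). Of 14 TGF-beta and BMP targets, 6 rose, including Ctgf (3.90 ± 0.287), and 5 fell (6 and 5 adjusted over the list alone; adjusted p = 0.29; median -0.025, mean 0.648, test upward, and 0.0127 by fry). Of 9 hedgehog genes, 2 rose, the transducer Smo (1.83 ± 0.109) and Sufu (1 ± 0.121), while the target Gli1 was at -0.05 (adjusted p = 0.739; 2 adjusted over the list alone; list adjusted p = 0.134, 0.0106 by fry and 0.03 without adenocarcinoma replicate 4). Of 17 gastric transcription factors, 5 fell, led by Klf4 (-1.95 ± 0.159) and Foxa3 (-1.53 ± 0.264), and Pdx1 rose (1.40; 5 and 1 adjusted over the list alone; adjusted p = 0.554, and 0.00927 by fry).

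Of 20 genes often altered in gastric tumours, 7 rose, led by the cell cycle inhibitor Cdkn2a (1.58 ± 0.165), and Cdh1 and Smad4 fell (8 and 2 adjusted over the list alone; median 0.275, camera adjusted p = 0.0321, adjusted p = 0.37 with an estimated correlation). The list was not called after cyclic loess (0.168), without the dimmest 30% of genes (0.19), or without adenocarcinoma replicate 2 (0.092) or normal replicate 3 (0.0506). Smad4, a mediator of TGF-beta signals, fell by 0.525 ± 0.171 (adjusted p = 0.0369), a call lost after centring on receptor genes (0.192), with a replicate block (0.0621) and in 7 of the 8 leave-outs, all but that of adenocarcinoma replicate 3 (0.0593 to 0.0885). Trp53 was at -0.40 ± 0.160 (adjusted p = 0.0713), and was called after median centring (0.0182) and cyclic loess (0.0467). Of 22 p53 targets, 5 rose, including Plk2 (1.88 ± 0.218), and 6 fell, including the cell cycle inhibitor Cdkn1a (-1.43 ± 0.291; 5 and 6 adjusted over the list alone; adjusted p = 0.693). The median of the p53 list was 0 and its test upward, and the test turned downward after cyclic loess (0.794) and centring on receptor genes (0.977).

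Lists for neighbouring tissues gave no list call. Of 19 pancreatic acinar genes, 7 fell (7 adjusted over the list alone; adjusted p = 0.284, and 0.00936 by fry), led by colipase (Clps, -3.80 ± 0.145) and syncollin (Sycn, -3.63 ± 0.253). Of 20 squamous forestomach genes, 5 fell and 2 rose (3 and 1 adjusted over the list alone; adjusted p = 0.604; median -0.225, mean 0.0925, test downward). Involucrin (Ivl) rose by 1.88 ± 0.518, a call lost without normal replicate 3 (0.0521), and the fall of Krt13 (-0.60 ± 0.215) was lost in all 8 leave-outs (0.0519 to 0.101), after cyclic loess (0.0976), 32 units added (0.0614), the mean of probe sets (0.0504) or centring on receptor genes (0.185), and with array weights (0.0849) or a replicate block (0.1). Of 14 enteric neuron and glia genes, 3 fell (1 adjusted over the list alone; adjusted p = 0.595): Nefm (-0.525 ± 0.116), Tubb3 (-0.275) and Sox10 (-0.30 ± 0.106). Nefm was at or below background in all 4 adenocarcinomas, and its fall was not called after centring on receptor genes (0.0503), and that of Sox10 was lost after cyclic loess (0.058), after centring on receptor genes (0.424), with trend and robust (0.0553), with added noise (0.0735), without the dimmest 30% of genes (0.0528) and without adenocarcinoma replicates 1 and 2 and normal replicates 1, 3 and 4 (0.0997 to 0.122). Of 11 adipocyte genes, only the lipase Lpl fell (-2.70 ± 0.496; 1 adjusted over the list alone; adjusted p = 0.919). None of 7 red blood cell genes was called (0 adjusted over the list alone). The red cell list (median 0.95, adjusted p = 0.411) passed without adenocarcinoma replicate 1 (0.00189), where the globin gene Hbb-b1 was at 9.0 against 12.5 to 13.2 in the other adenocarcinomas.

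With the preset correlation, 15 of the 37 lists were higher and 4 lower. With an estimated correlation camera called 0 lists, with 7 at an unadjusted p under 0.05, and fry called 18 of the 19 in the same direction. Of 1054 gene ontology terms, 197 were higher and 37 lower, and with an estimated correlation 0 passed, with 81 at an unadjusted p under 0.05. The leading higher terms were kinetochore (43 of 71 genes rose, adjusted p = 2.3e-09), centromeric region of the chromosome (61 of 109, 5.34e-09), mitosis (92 of 191, 5.34e-09) and rRNA processing (38 of 70, 2.02e-08). The leading lower terms were respiratory chain (45 of 54 genes fell, 3.31e-08) and mitochondrial inner membrane (152 of 300, 2.37e-05). Each of these 6 terms had an adjusted p = 0.576 with an estimated correlation.

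Adenocarcinomas varied more among themselves than normal samples did. The median SD of a gene was 0.189 among adenocarcinomas and 0.129 among normal samples, a ratio of 1.47. The two-sided exact permutation p was 0.0286 (2 of 70 assignments), the smallest that this test can give, since each assignment counts with its mirror. The muscle gene Des ranged from 8.8 to 12.2 in the adenocarcinomas and from 7.1 to 7.7 in normal mucosa. The ratio was 1.34 without any 1 of the 4 adenocarcinomas (exact permutation p of 0.2, 0.2, 0.229 and 0.171 without replicates 1 to 4) and 1.24 without normal replicate 4 (0.143), which ended the call.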

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

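All tests of explanations in the first 3 paragraphs were chosen after the results were seen; the counts over splits of the arrays were planned.

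Xist and 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y) parted the groups. Xist loss in tumours of females would leave the Y-linked genes at the level of normal mucosa, but the smallest gap between the lowest adenocarcinoma and the highest normal sample was 1.8 on the log2 scale (Kdm5d). Exchange of 1 or 2 samples between the groups is argued against by the correlations over all genes, of which the lowest within a group was 0.961 and the highest across groups 0.923. The same sex in both groups is argued against: all 4 Y-linked genes lay over 1 log2 unit higher in every adenocarcinoma. Xist lay between 6.2 and 6.6 in the adenocarcinomas and between 11.6 and 12.7 in the normal samples. These genes raised the question and so restate the pattern, and the labels give no sex to check it against. Which of the other changes come from sex stays open.

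Parietal, chief and pit cell genes were lower (39 genes, median -2.15). A smaller share of epithelial cells may be weighed first, but the epithelial junction and keratin genes had a median of -0.125 (95% bootstrap interval -0.425 to 0.1). Of these 23 genes 1, Cdh1, fell as far. The interval is for the median over the list's genes. As 5 of them rose and 5 fell, the list gauges the epithelial share only roughly. Normal antral tissue in place of corpus would keep the pit cell genes, whose median was -1.45 (-3.4 to -0.925). A tumour of the antrum could lack pit cells too, so this fall cannot decide the region of origin. For the parietal and chief cell genes an antral origin cannot be told apart from loss of these cells: Gast, the hormone of the antrum, was at 0.325, and a tumour of the antrum can lack the cells that make it. Loss of mature gland cells in adenocarcinoma stays an open hypothesis, confounded with sex and with any difference in age or genotype.

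Most falls were small: 4418 of the 5099 (86.6%) were under 2-fold. Olfactory and vomeronasal receptor genes, which the stomach is not known to use, were lower in 21.4% of cases (286 of 1338, with 4 higher and 0 lower by 2-fold), against 28.3% of 4763 other genes at their level. The medians of the background control probes were 6.0 to 6.2 in adenocarcinoma and 6.2 to 6.4 in normal mucosa. Background or normalisation of the arrays could therefore account for many small falls of dim genes. The number of receptor genes lower moved with the scaling, to 36 after cyclic loess and 804 after median centring. A real shift of dim genes in adenocarcinoma was not tested.

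Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave as many called genes (9041, highest other 0). It also gave the most called at 2-fold (2116, highest other 0). Its share of 0.0286 is the smallest that 35 splits can give. The other splits mix both tissues in each group, which raises their spread, so their count of 0 does not exclude chance. For gene ontology terms the real split was also highest (1 of 35, 234 terms). Another split gave 213, so this count does not exclude chance either. For the number of gene lists called chance cannot be excluded: 10 of 35 splits gave at least 19, and the highest other gave 24.

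Single arrays far from the rest of their group were found in 7 of 186 groups tested, and chance gives about 1 in 20; 52 groups with a range under 0.3 were left out because of the rounding. Adenocarcinoma replicate 2 had Gsdma2 at 8.5 (others 6 to 6.2). Adenocarcinoma replicate 1 had Atp4a at 8.1 (others 9 to 9.1), Cxcr2 at 8.4 (others 8.9 to 9) and a mean over the mucous neck cell genes of 10.42 (others 11.74 to 11.94). Among normal samples, Fabp2 was at 11.2 in replicate 4 (others 10.6 to 10.7), Col12a1 at 7.6 in replicate 1 (others 7.1) and Acta2 at 9 in replicate 2 (others 8.4 to 8.5). Outside the comparison, 895 of 3373 gene probe sets without a symbol were called, 84 higher and 811 lower, and 33 and 44 of them changed at least 2-fold.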

How the results depend on the processing

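Centring on receptor genes, removal of X and Y genes, unique probe sets and added noise were chosen after seeing the data. Named genes kept their direction in every setting run; 1639 of their values kept their side of the threshold, 70 lost a call and 5 gained one. Of single list results, 776 were alike, 35 lost and 17 gained a call, and 22 turned direction, all of them lists that were not called. Genes lower numbered 9272 after median centring, 3239 after cyclic loess, 3180 without the dimmest 30% of genes (fewer genes tested), 1577 after centring on receptor genes and 1912 at an adjusted p under 0.01, where genes higher numbered 2376. Higher terms numbered 111 after cyclic loess, 84 without the dimmest genes and 114 at 0.01, where 14 were lower. With an estimated correlation 0 lists and 0 terms passed in either direction, and fry called 8 lists lower. Apart from the stricter threshold, the smaller gene set and the set tests, whose construction sets the count, the cause was not tested. Leaving out 1 array gave 2945 to 3966 genes higher, 2975 to 5456 lower, 1297 to 1539 and 630 to 692 at 2-fold, 13 to 17 lists higher and 4 to 6 lower, 177 to 212 and 28 to 40 terms, and a spread ratio of 1.24 to 1.89. The turned list tests, as adjusted p, were adipocytes (0.88 median centring, 0.936 array weights, 0.96 and 0.836 without adenocarcinoma replicates 1 and 4), epithelial junctions (0.581 loess, 0.605 without dim genes, 0.908 weights, 0.754, 0.852 and 0.962 without adenocarcinoma replicates 1 and 2 and normal replicate 3, 0.914 receptor centring), neurons and glia (0.906 loess), T and NK cells (0.739 loess, 0.752 without adenocarcinoma replicate 1), p53 targets (0.794 loess, 0.628 without dim genes, 0.993 without adenocarcinoma replicate 3, 0.977 receptor centring), mast cells (0.96 without adenocarcinoma replicate 1) and intestinal epithelium (0.853 without adenocarcinoma replicate 4, 0.73 fry, 0.755 receptor centring). Over the leave-outs these tests ran from 0.289 to 0.962 (adipocytes), 0.318 to 0.802 (T and NK cells), 0.59 to 0.993 (p53 targets), 0.248 to 0.96 (mast cells) and 0.307 to 0.853 (intestinal epithelium). Xist was at 6.2 to 6.6 in the adenocarcinomas and at 11.6 to 12.7 in the normal samples. All 4 Y-linked genes lay over 1 log2 unit higher in every adenocarcinoma. These values argue against a tumour and a normal sample from the same animal. Whether the replicate numbers pair the samples in another way was not settled. The r of their deviations was -0.18, 0.095, 0.16 and 0.038, against -0.2 to 0.16 over all cross pairs. Of 4 adenocarcinomas, 2 correlated best with their own number. With the replicate block 3578 genes were higher and 4519 lower. Slide or scan date and the identical value table were not run; array weights, trend and robust, block and threshold give no spread ratio. The values are rounded in steps of 0.1.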

Other observations

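Gene families chosen after the values were seen added to the lists. Of 16 complement and acute-phase genes, 13 rose, among them C3 (4.45 ± 0.187) and the lipopolysaccharide binding protein Lbp (4.43 ± 0.165), while Saa1 and Saa2, at or below background on all 8 arrays, were called lower; after cyclic loess and after centring on receptor genes 13 rose and 0 fell. Of 7 Reg genes, 3 rose: Reg3g, Reg3b and Reg1 (4.40 ± 0.558), and Reg4 was at -0.35 (adjusted p = 0.0553); cyclic loess and centring on receptor genes gave 4 rises, and median centring 3 rises and 1 fall. Of 7 insulin-like growth factor binding proteins, Igfbp7 (4.18 ± 0.175), Igfbp4 (3.93 ± 0.217), Igfbp3 (3.85 ± 0.347) and Igfbp5 (2.75 ± 0.380) rose, and Igfbp2 (-1.48 ± 0.210) and Igfbp1 (-0.375 ± 0.106) fell. After cyclic loess and after centring on receptor genes 1 of these falls was called. Of 13 claudins, 6 rose, with Cldn2 (3.40 ± 0.487), Cldn7 and Cldn4 highest, and 2 fell, Cldn8 (-1.48 ± 0.321) and the stomach claudin Cldn18 (-0.575 ± 0.0763); cyclic loess gave 7 rises and centring on receptor genes 9. No called gene of these families changed sign under these scalings.

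The TGF-beta and BMP target list split by gene. In a family chosen after the values were seen, all 6 Id proteins and inhibitory Smads measured fell: Id1 (-1.90 ± 0.212), Id3 (-1.70 ± 0.242), Smad6 (-1.15 ± 0.159), Smad7 (-1.05 ± 0.144), Id4 (-0.95 ± 0.0933) and Id2 (-0.425 ± 0.114). Of these, Id4 is not on the target list. After centring on receptor genes 5 of the 6 were called. The targets that rose, among them Ctgf, Tgfbi (2.90), Ltbp2 (2.70), Tgif1 (1) and Pmepa1 (0.95), include genes of matrix and matrix-bound proteins, and Tgfb1 itself rose by 2.20 ± 0.141. Outside the lists, ribosome terms were also higher: 21 of 28 genes of the cytosolic small ribosomal subunit rose (camera adjusted p = 3.31e-08, adjusted p = 0.576 with an estimated correlation).

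Some intestinal and goblet cell genes were higher in 1 adenocarcinoma than in the other adenocarcinomas. Replicate 4 had Muc2 at 12.2 (others 7.6 to 8), Tff3 at 13.5 (others 8.3 to 10.6) and Zg16 at 12.0 (others 6.9 to 7.6), though normal replicate 4 also had Zg16 at 11.1. None of these 3 genes was called between groups (adjusted p = 0.979, 0.428 and 0.624). The mean over the intestinal list was 10.07 in adenocarcinoma replicate 4 and 8.376 to 9.441 in the other adenocarcinomas. It was 9.865 in normal replicate 4 and 8.982 to 9.359 in the other normal samples, so a high mean was not particular to this tumour. These genes were picked because of replicate 4, and no test was run on the difference.

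X-linked genes were set beside autosomal genes without a test of the difference. Of 839 genes on X, 23.2% were lower and 14.1% higher, against 23.6% and 18.4% of autosomal genes. Among 4 X-linked genes known to escape inactivation, Kdm6a and Kdm5c were each lower by a log2 change of -0.55 (adjusted p = 0.00587 and 0.0243), Ddx3x was at -0.125 (0.355) and Eif2s3x at 0.225 (0.358). Neither of both falls was called after centring on receptor genes.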
